A study of Mus musculus with 21 samples.

How the data were processed

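RNA was measured by bulk RNA sequencing in 21 libraries of sorted mouse intestinal Lgr5 cells, in 7 groups of 3. Per the labels' protocols, crypts were dispersed, the brightest Lgr5-EGFP cells were collected in bulk by flow sorting, total RNA was isolated with a phenol reagent, cDNA was made with SMART-Seq v4, and paired-end libraries were made with Nextera XT. This kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

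The authors deposited 1 table of whole-number read counts for 37310 genes and 92 ERCC spike-in RNAs, and 1 table of TPM values for the same genes. Per the submitters' processing notes, STAR 2.4.2a, HTSeq 0.6.1 and edgeR were used with genome build mm9; the role and settings of each, the annotation release and the version of edgeR are not given in the sources used here. The deposited counts are not normalised. The deposited TPM values are those counts divided by 1 length per gene and rescaled in each library: over 6979 genes with over 200 counts in every library, the log2 ratio of count to TPM, centred in each library, varied between libraries by an SD of at most 6.4e-10 against a tolerance of 1e-06. TPM therefore carries no information beyond the counts other than another scaling. Gene symbols and identifiers are those of the files. No column of per-sample values was left unmapped to a sample.

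Counts assigned to genes ranged from 19889795 to 115435120 per library, and 17764 to 21897 genes had a count. PCR copies were not marked with molecular identifiers, so counting intervals and floors cover counting error only. The levels of Xist and of Y-linked genes matched the labelled sex in 21 of 21 libraries. No pair of replicates was a repeated library: the chi-square statistic per degree of freedom between replicates of a group was 48.06 or more. The labels describe each library as a separate mouse sample of its group. The p-values rest on the spread between libraries within groups, pooled over the 7 groups of the fit. That spread was not alike in all groups. Replicates correlated in log2 CPM at 0.936 to 0.952 in NWD1 and at 0.975 to 0.979 in NWD1Ca.

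The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, on the deposited counts with TMM scaling. All 21 libraries entered 1 fit with a mean per group and a term for sex, because the sexes are spread unevenly over the groups. The filterByExpr function kept 16050 genes, and spike-ins stayed out of library sizes and gene tests. Benjamini-Hochberg adjustment was applied over the 16050 genes of a comparison, with 0.05 as the threshold. Every adjusted p of a gene comes from this test unless another is named, every log2 fold change is the fitted one with its standard error, and CPM values use TMM-scaled library sizes. Means over libraries are given with n = 3.

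Before the data were examined, 9 comparisons, the alternatives and 39 gene lists were fixed; 38 lists had at least 5 tested members. The lists cover intestinal cell types, cells that a sort could carry over, and metabolic, cell cycle, signalling and stress pathways. Lists were tested with camera in limma 3.58.1 on the same counts and design, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated for each list. With an estimated correlation none of the 154 list calls was left. A list holds the identifiers of its genes' symbols; Ciita and H2-Q2 have 2 tested identifiers each, and both lists that hold them, MHC class II and class I presentation, were also tested with each gene taken once, an alternative chosen after the data were seen. Members past the threshold are counted over all genes and adjusted over the list alone. Shared control libraries were treated by simulating unchanged groups against the same controls in 20 simulations.

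Genes named in the text follow a rule fixed in advance for 6 comparisons, namely NWD1, NWD2, AINlowVitD and AIN_VdrKO against AIN, and NWD1Ca and NWD1VitD against NWD1. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups' libraries (10% of unchanged genes would show none by chance), leaving out sex-linked genes, predicted genes, Rik clones and LOC identifiers. It adds up to 4 members of each list with the smallest p among those past the threshold, or 2 where a list passed camera with none. Vdr, Cyp24a1, Trpv6, S100g, Lgr5 and Ppargc1a are named in each of the 9 planned comparisons in which they were tested. Other genes are said to be chosen after their values were seen. Some genes that meet the rule are not reported here. Genes of families with near-identical copies may share or lose reads in counting, so single members of the Defa and Reg3 families, Mt1 and Mt2, H2 genes, Gsta1, Acot1 and Acot2, Serpina1b, Gapdh and ribosomal protein genes are uncertain.

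Alternatives set before the data were examined were no filter on low counts, DESeq2 size factors within edgeR, DESeq2 1.42.0 in place of edgeR, limma on log2(TPM + 1) and on log2(TPM + 0.1), no sex term, only the 2 groups compared, a block for the replicate number, and each replicate left out in turn. Chosen after the data were seen were 2 full comparisons (NWD1VitD against NWD1Ca, AIN_VdrKO against AINlowVitD), a count for AINlowVitD against NWD1Ca, a fit of only the 9 libraries on the same side of the largest difference between libraries, fits without the NWD1 libraries with over 20% spike-in counts, without AIN_VdrKO 3 or without AIN 1, AIN 2 and NWD1 1, tests of the spike-ins with edgeR, and a correction of each library for GC content and gene length. GC content came from GENCODE M21 transcripts (GRCm38), matched by gene identifier for 95.6% of the tested genes. That build differs from mm9, so no coordinates were used.

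On simulated counts for NWD1 against AIN with 15281 genes, of which 100 were changed 2-fold and 100 were changed 4-fold, edgeR recovered 13 and 80 of them with 4 unchanged genes called. DESeq2 recovered 23 and 91 with 28 unchanged genes called, and limma on log2(TPM + 1) recovered 13 and 73 with 4. Changes of 2-fold were thus mostly missed in the simulation of this comparison, and the other comparisons were not simulated. Genes were simulated independently of each other, without the structure between libraries seen in the real data. The number of unchanged genes called there may therefore be too low for the real comparison.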

Results

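Lgr5 marks the stem cells at the base of the intestinal crypt. RNA was sequenced from sorted Lgr5-EGFP cells of Lgr5EGFPcre-ERT2 mice that were fed a purified diet from weaning to 3 months of age. The 7 groups of 3 libraries were AIN (AIN76A, a purified control diet), NWD1, NWD2, NWD1Ca (NWD1 with calcium given in the labels as 7.0 mg/g), NWD1VitD (NWD1 with vitamin D given as 2.3 IU/g), AINlowVitD (AIN with vitamin D given as 0.11 IU/g) and AIN_VdrKO (AIN76A-fed mice labelled as lacking the vitamin D receptor). The labels write these doses per g body weight, and the makeup of NWD1 and NWD2 is not given in the sources used here. AIN, NWD2, NWD1, NWD1VitD and AINlowVitD held mice of both sexes, NWD1Ca only females and AIN_VdrKO only males. Between 19889795 and 115435120 counts per library fell on genes. The study asks how diet affects intestinal Lgr5 stem cells, and 9 comparisons between these groups were planned.

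The libraries fell into 2 sets that did not follow the base diet. The first principal component held 43.9% of the variance and separated AIN, NWD1 and NWD2, called the first set here, from NWD1Ca, NWD1VitD and AINlowVitD, called the second set, with AIN_VdrKO between them. Within the first set AIN 1, AIN 2 and NWD1 1 stood apart, at -38.6, -40.2 and -42.6 on this component, while AIN 3, NWD1 2, NWD1 3 and the NWD2 libraries lay between -104.3 and -90. Mitochondrial ribosomal RNA took 0.2335% to 0.9648% of gene counts in the first set, 2.949% to 5.067% in the second set and 1.379% to 2.804% in AIN_VdrKO. The 10 most abundant genes took 5.332% to 8.37% of counts in the first set, 14.13% to 20.45% in the second set and 8.617% to 13.51% in AIN_VdrKO. ERCC spike-ins, synthetic RNAs that no diet can change, differed too. Of 77 spike-ins tested with edgeR, 63 (81.8%) had a different relative abundance between 8 libraries of the first set and 9 of the second. AIN 2 held 12 spike-in counts and was left out of the spike-in tests. A comparison within a set changed 0 of 77 spike-ins, and one across the sets changed 44 to 54, or 57.1% to 70.1%, while AIN_VdrKO differed from AIN in 7 and from AINlowVitD in 36. For AIN these tests rest on AIN 1 and AIN 3, which lay apart on the first principal component. A comparison of group means that mix such libraries cannot exclude a preparation difference within the first set. The labels give no batch for the sets. They give the index pair of each library, and 4 pairs were carried by 9 libraries. AIN 2 and NWD2 1 of the first set carried the same pair, as did NWD1Ca 2, and libraries with the same pair cannot be told apart in a shared lane, so the first set was not sequenced in a single lane. The groups other than AIN_VdrKO lay wholly in 1 set, so a value within each set cannot be had for the comparisons across them, in which set and diet cannot be told apart.

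**Figure D1:**
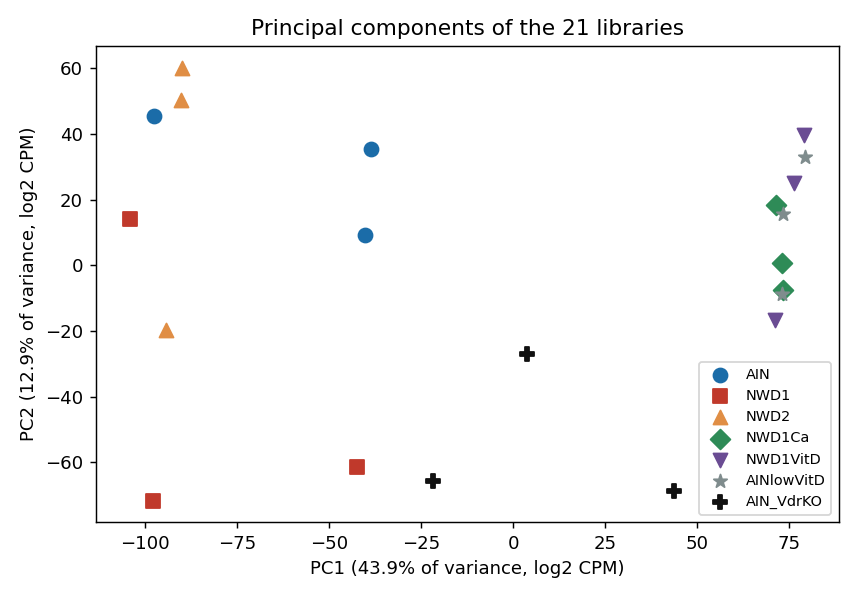
Principal components of log2 CPM in the 21 libraries, 1 point per library coloured by group, with component 1 (43.9% of the variance) and component 2 (12.9%) on the axes. AIN, NWD1 and NWD2 lie on one side of component 1, NWD1Ca, NWD1VitD and AINlowVitD on the other, and AIN_VdrKO between them.

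**Figure D2:**
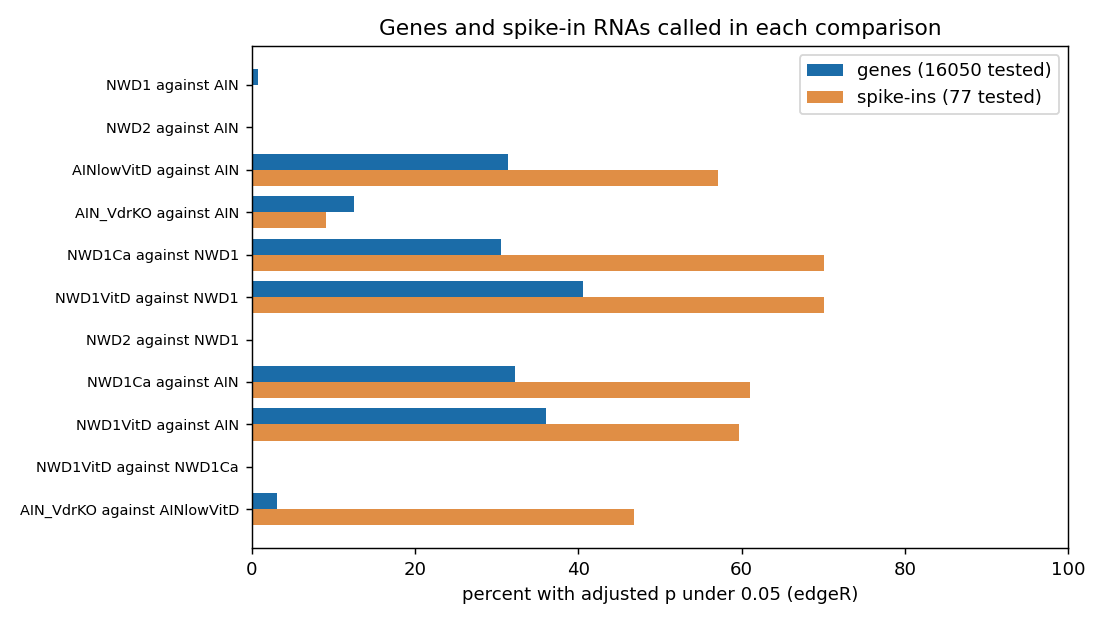
Percent of 16050 genes and of 77 spike-ins with an adjusted p under 0.05 in each comparison (edgeR quasi-likelihood test). No spike-in changed in NWD1 against AIN, while 70.1% changed in NWD1Ca against NWD1 and in NWD1VitD against NWD1.

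NWD1 against AIN asks what the NWD1 diet does to Lgr5 cells relative to the control diet. Trpv6 (ENSMUSG00000029868.7), the apical calcium channel of the intestine, had 1071, 796 and 853 counts in the NWD1 libraries and 2, 2 and 0 in AIN, a mean of 16.8 ± 3.40 CPM (SD, n = 3) against 0.0203 ± 0.0199. Its pooled ratio was 784 (95% counting interval 306 to 2880), and its fitted log2 fold change was 9.41 ± 1.22 (SE, adjusted p = 0.00967, edgeR quasi-likelihood test). The metallothionein genes Mt1 and Mt2, which bind zinc and copper, rose as well, and 4 of 32 enterocyte genes fell, a list call that was lost with an estimated correlation (adjusted p = 0.286). In all, 17 genes rose and 106 fell of 16050 tested, with 2436 at an unadjusted p under 0.05. On log2(TPM + 1), where the log2 fold changes of single genes shifted by a median of 0.40, limma called 185 higher and 47 lower. The NWD1 1 and NWD1 2 libraries held 24.7% and 20.4% spike-in counts against 5.18% in AIN 1 and 1.36% in AIN 3, and without these 2 libraries 1 gene was called. Fits without them hold 1 NWD1 library, assumed to vary like the other groups, so calls lost there can come from the size of that group alone. AIN 1, AIN 2 and NWD1 1, which stood apart on the first principal component, gave 1659 called genes when set against the other 3 libraries. Without them edgeR called 0 genes in NWD1 against AIN, with 2579 at an unadjusted p under 0.05 and the lone AIN library assumed to vary like the other groups. Without AIN 1 alone, Trpv6 had 10.05 ± 1.56 (adjusted p = 0.0704).

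Among the rises, Mt2 changed by 4.40 ± 0.87 on the log2 scale (adjusted p = 0.0274), from a mean of 8.48 ± 4.09 CPM (SD, n = 3) on AIN to 145 ± 28.2 on NWD1. Mt1 changed by 2.13 ± 0.48 (adjusted p = 0.0455), the secreted phospholipase Pla2g5 by 3.13 ± 0.55, the matrix protein Prelp by 2.17 ± 0.36, the transcription factor Zfhx3 by 1.56 ± 0.28 and the Wnt coactivator Bcl9l by 1.39 ± 0.32. The chromatin gene Chd7 rose by 0.92. The calls of Zfhx3, Bcl9l, Chd7 and, among the falls, Mogat2 and Nqo1 were lost with the correction for GC content and length.

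Of 32 tested enterocyte genes, 4 fell over all genes and 27 when adjusted over the list alone, with a median log2 fold change of -2.15. Camera gave this list an adjusted p = 4.12e-22, and adjusted p = 0.286 with an estimated correlation. They included Sis, the sucrase-isomaltase of the brush border (-3.81 ± 0.75), Khk of fructose metabolism (-2.82 ± 0.46) and Mogat2 of fat absorption (-2.35 ± 0.54). Mean Sis was 2813 CPM on AIN and 217.2 on NWD1. The median enterocyte gene stood at a log2 CPM of 8.64, 8.84 and 9.03 in the AIN libraries and 6.13, 6.32 and 7.47 in NWD1, the first 2 of these being the libraries high in spike-ins. Without them, with NWD1 3 as the lone NWD1 library, the median was -1.67, no member passed over all genes and 1 fell when adjusted over the list alone. Largest falls outside the list included G6pc, the last enzyme of glucose release (-5.20 ± 1.13), the acetyltransferase Nat8 (-3.82), the glutathione transferase Gsta1 (-3.59), the apolipoproteins Apol9a (-3.19) and Apol10a (-3.05), and the microRNA gene Mir215 (-3.16).

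**Figure D3:**
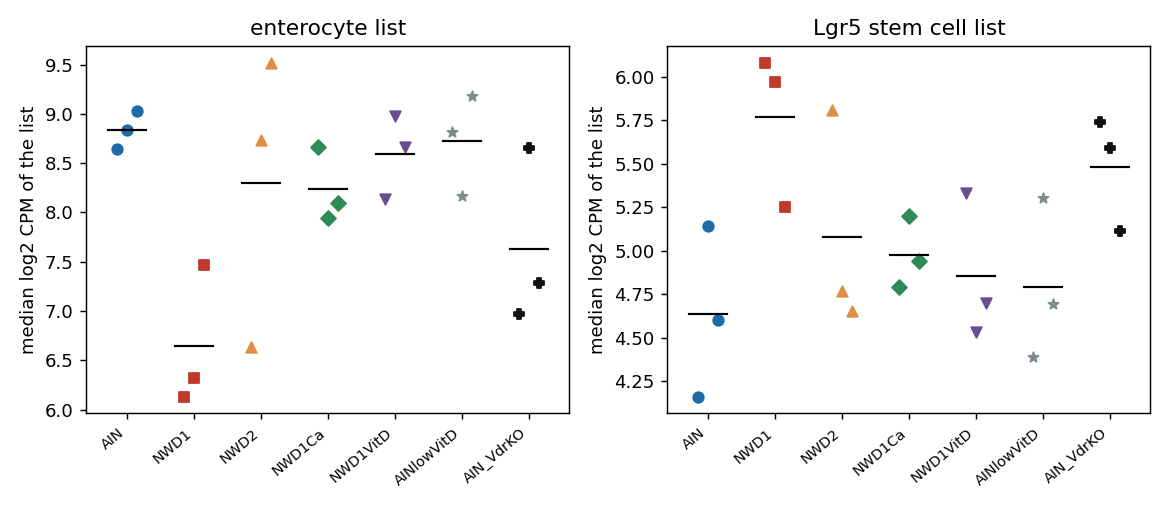
Median log2 CPM of the enterocyte list and of the Lgr5 stem cell list in each library, by group, with a line at the group mean. All 3 NWD1 libraries lie below the 3 AIN libraries for the enterocyte list, with a lowest AIN value of 8.64 and a highest NWD1 value of 7.47.

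The 25 tested Lgr5 stem cell genes had a median log2 fold change of 1.01 (camera adjusted p = 8.57e-16, adjusted p = 0.285 with an estimated correlation). None passed over all genes and 12 were higher when adjusted over the list alone. Tnfrsf19 had 1.94 (adjusted p = 0.0525), Sox9 1.39 (adjusted p = 0.0864) and Lgr5 itself 1.24 ± 0.49 (adjusted p = 0.227). Without the 2 libraries high in spike-ins the median was 0.87, with 1 member higher when adjusted over the list alone. Wnt target genes had a median of 0.76, with 0 of 25 over all genes and 7 adjusted over the list alone (camera adjusted p = 1.66e-08, adjusted p = 0.285 with an estimated correlation). Myc had 1.46 (adjusted p = 0.0659). Of 19 Notch pathway genes, 0 passed and 3 were higher adjusted over the list alone (median 0.61, camera adjusted p = 0.00068, adjusted p = 0.286 with an estimated correlation). Notch1 had 1.27 (adjusted p = 0.0560) and Atoh1, the driver of secretory cells, 1.06 (adjusted p = 0.0587).

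Interferon response genes had a median of -1.15. Of 38 tested, 2 fell over all genes, Ifit3 (-4.96 ± 0.91) and Ifi44 (-4.40 ± 0.89), and 18 when adjusted over the list alone (camera adjusted p = 3.03e-13, adjusted p = 0.292 with an estimated correlation). Without the 2 libraries high in spike-ins 0 of 39 fell on either count, with a median of -1.05. Genes of antigen presentation by MHC class I had a median of -0.65, with 0 of 24 identifiers over all genes and 6 adjusted over the list alone, (camera adjusted p = 1.38e-05, adjusted p = 0.371 with an estimated correlation). With H2-Q2 taken once 5 of 23 genes passed over the list alone (camera adjusted p = 3.5e-05, adjusted p = 0.378 with an estimated correlation). Il18, a cytokine of the epithelium, fell by 3.11 and the lectin Reg3a by 3.17. The glycolysis genes Pkm2 (-1.81 ± 0.34), Gpi1 (-1.64 ± 0.33) and Gapdh (-1.69 ± 0.38) fell, 3 of 23 over all genes and 10 adjusted over the list alone, where 1 rose (camera adjusted p = 3.42e-05, adjusted p = 0.371 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.77, with 0 of 76 passing over all genes and 3 adjusted over the list alone (camera adjusted p = 2.21e-14, adjusted p = 0.531 with an estimated correlation). TCA cycle genes had -0.63, with 0 of 24 and 8 (camera adjusted p = 1.67e-07, adjusted p = 0.349 with an estimated correlation). These falls were smaller on log2(TPM + 1). The medians there were -0.61 for interferon response, -0.17 for MHC class I, -0.14 for glycolysis, -0.33 for oxidative phosphorylation and -0.2 for TCA cycle genes. Without the 2 libraries high in spike-ins 3 TCA cycle genes fell when adjusted over the list alone, and 1 glycolysis gene rose and 8 fell. Ppargc1a, a regulator of mitochondrial biogenesis, had -1.73 ± 0.54 (adjusted p = 0.112).

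Of 26 tested vitamin D receptor target and calcium transport genes, Trpv6 and Mt1 rose over all genes, while 3 rose and 2 fell adjusted over the list alone. The median of that list was -0.25 while camera gave the direction up (adjusted p = 0.428), and the median was 0.05 on log2(TPM + 1). Vdr (ENSMUSG00000022479.9) had 0.91 ± 0.35 (adjusted p = 0.213), and S100g (ENSMUSG00000040808.4), the calcium carrier calbindin-D9k, 2.52 ± 0.94 (adjusted p = 0.195). Cyp24a1, the enzyme that degrades vitamin D, had too few counts to be tested in any comparison. The number of genes called rested on single libraries, with 0 without AIN 1, 1 without NWD1 2, 18 without NWD1 1, 48 without AIN 3 and 274 without NWD1 3. It was 3 in a fit of the 9 first-set libraries, 13 with only the 2 groups and 802 with DESeq2.

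**Figure D4:**
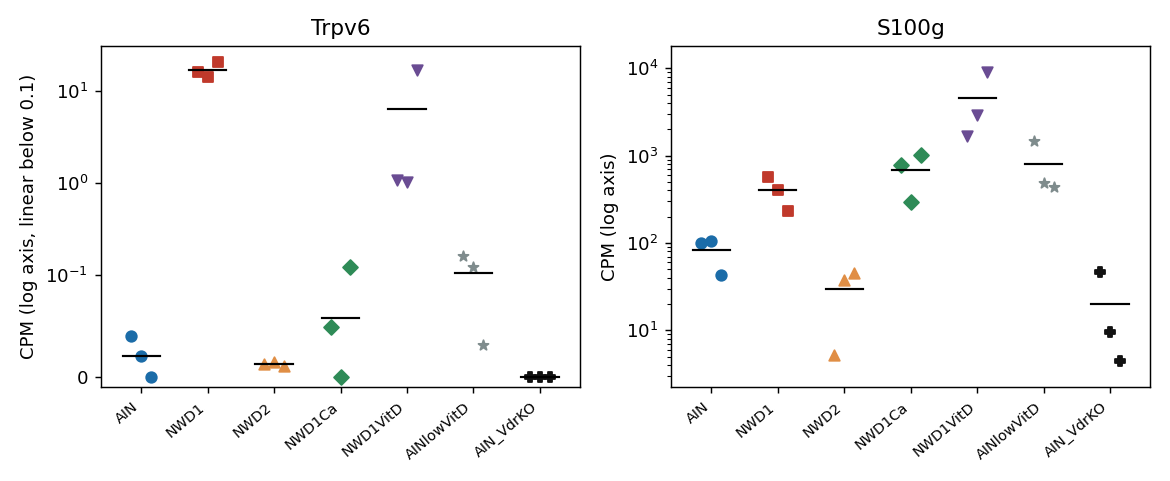
Trpv6 and S100g in CPM per library on a log axis (linear below 0.1 for Trpv6), by group, with a line at the group mean. All 3 NWD1 libraries lie far above AIN and NWD2 for Trpv6, and S100g is highest in NWD1VitD and lowest in NWD2 and AIN_VdrKO.

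NWD2 set beside AIN and NWD1 asks what the other modified diet does. No gene differed between NWD2 and AIN by edgeR, with 1099 at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma on log2(TPM + 1). Trpv6 had 1, 1 and 1 counts in NWD2, did not differ past the threshold from the 2, 2 and 0 counts in AIN (-0.69 ± 1.66, adjusted p = 0.936) and was the gene that differed from NWD1, at -10.09 ± 1.25 (adjusted p = 0.00491); the pooled ratio of NWD1 to NWD2 was 1270 (95% counting interval 433 to 6140). Against NWD1, 1717 genes had an unadjusted p under 0.05, DESeq2 called 275 higher and 69 lower, and limma on log2(TPM + 1) called 6 higher and 21 lower. Without NWD2 2 or NWD2 3 its fold change stayed near that value, at -10.13 ± 1.55 and -10.08 ± 1.58, but did not pass (adjusted p = 0.104 and adjusted p = 0.136). AIN 1, AIN 2 and NWD1 1 stood apart from all NWD2 libraries on the first principal component, and without them edgeR called 0 genes in NWD2 against AIN, with 398 at an unadjusted p under 0.05 and the lone AIN library assumed to vary like the other groups, and 2 in NWD2 against NWD1. S100g had -3.90 ± 0.94 (adjusted p = 0.117), Ppargc1a 1.37 (adjusted p = 0.335), Vdr -0.24 (adjusted p = 0.828) and Lgr5 -0.19 (adjusted p = 0.908). Mt2 had -3.68 and Mt1 -2.04 (adjusted p = 0.114 for both), these 2 being chosen for this comparison after their values were seen. Without NWD1 3, S100g passed at -4.39 ± 0.99 (adjusted p = 0.0348).

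Enterocyte genes had a median of 2.13 in NWD2 against NWD1, with 0 of 32 passing over all genes and 28 higher adjusted over the list alone (camera adjusted p = 1.02e-20, adjusted p = 0.539 with an estimated correlation). The groups overlapped, since the list median was 6.63 log2 CPM in NWD2 1 and 7.47 in NWD1 3. Lgr5 stem cell genes had -0.77, with 6 of 25 lower adjusted over the list alone (camera adjusted p = 2.15e-11, adjusted p = 0.539 with an estimated correlation), and interferon response genes 0.82 (camera adjusted p = 4.57e-09, adjusted p = 0.764 with an estimated correlation). Against AIN, the median of 32 enterocyte genes in NWD2 was -0.13 and turned to 0.10 on log2(TPM + 1). Oxidative phosphorylation genes had -0.88 against AIN with 0 of 76 passing on either count (camera adjusted p = 1.02e-29, adjusted p = 0.869 with an estimated correlation), among them Ndufb4 at -1.48 and Cycs at -1.23 (adjusted p = 0.718 for both). Cytosolic ribosomal protein genes had -0.79 (camera adjusted p = 2.22e-19, adjusted p = 0.869 with an estimated correlation). On log2(TPM + 1), where the log2 fold changes of single genes shifted by a median of 0.38, these 2 lists had -0.38 and -0.25. Over all genes, log2 fold changes in NWD2 against AIN correlated with gene length at 0.36 (Spearman), so shorter genes tended to be lower in this comparison. Tuft cell genes had 0.92 (camera adjusted p = 0.000101, adjusted p = 0.869 with an estimated correlation). The tuft cell value rested on NWD2 2, where the median was 8.09 log2 CPM against 5.54 and 5.77 in the other NWD2 libraries and 6.35, 5.6 and 6.05 in AIN. Without NWD2 2 it was -0.19 (camera adjusted p = 0.618). Lgr5 had 1.05 (adjusted p = 0.718), Vdr 0.67 (adjusted p = 0.72), S100g -1.38 (adjusted p = 0.737) and Ppargc1a -0.36 (adjusted p = 0.886) against AIN, the last at 0.03 on log2(TPM + 1). Without AIN 3, 840 genes were called in NWD2 against AIN, and against NWD1 the number was 343 without NWD2 1, 337 without NWD1 3 and 0 without NWD2 2 or NWD2 3.

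AINlowVitD against AIN asks what less vitamin D in the control diet does, across the 2 sets of libraries. The metallothioneins Mt1 and Mt2, the defensin Defa24 and the hormones Sst and Sct rose. So did 48 of 76 oxidative phosphorylation genes and 58 of 78 cytosolic ribosomal protein genes, while 26 of 48 genes of G2 and M phase, 20 of 53 DNA repair genes and 13 of 24 TCA cycle genes fell, list calls that were lost with an estimated correlation (adjusted p = 0.974). In all, 2416 genes rose and 2614 fell, and 44 of 77 spike-ins (57.1%) changed as well. On log2(TPM + 1), where the log2 fold changes of single genes shifted by a median of -0.96, 733 were higher and 7368 lower, so the balance of directions depends on the scaling.

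Vdr fell by 1.08 on the log2 scale (SE 0.36, adjusted p = 0.0278), from 485.9 to 225.9 CPM, and S100g rose by 3.28 ± 0.90 (adjusted p = 0.0102), from 83.54 to 807 CPM. Both calls were lost with the correction for GC content and length, at -0.82 and 2.03. They were also lost without AIN 3, at -0.62 (adjusted p = 0.211) and 2.98 (adjusted p = 0.0532), and without AINlowVitD 1, at -1.17 (adjusted p = 0.0534) and 2.53 (adjusted p = 0.0586). Without AINlowVitD 3 Vdr had -0.76 (adjusted p = 0.171). Mt1 rose by 3.61 ± 0.50 (adjusted p = 0.000102), from 180.2 to 2176 CPM, and the tight-junction genes Cldn2 (-1.79 ± 0.35) and Cldn12 (-1.32 ± 0.32) fell. The calcium pump gene Atp2b1 had 1.02 (adjusted p = 0.00511) and turned to -0.14 on log2(TPM + 1). Of 26 vitamin D receptor target and calcium transport genes 4 rose and 5 fell, the same numbers adjusted over the list alone (median -0.44, camera adjusted p = 0.805). Trpv6 had 5, 2 and 1 counts (2.15 ± 1.44, adjusted p = 0.273), Lgr5 -0.29 (adjusted p = 0.694) and Ppargc1a -0.55 (adjusted p = 0.449).

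Of 76 oxidative phosphorylation genes 48 rose and 6 fell (50 and 7 adjusted over the list alone), with a median of 1.84 (camera adjusted p = 1.01e-13, adjusted p = 0.974 with an estimated correlation). Examples are Atp5k (3.61 ± 0.54), Ndufc1 (3.16 ± 0.47) and Ndufb2 (3.04 ± 0.44). Of 78 cytosolic ribosomal protein genes 58 rose and none fell, with 64 adjusted over the list alone (median 1.81, camera adjusted p = 2.46e-21, adjusted p = 0.974 with an estimated correlation), such as Rpl38 (2.82 ± 0.53) and Fau (2.49 ± 0.42). Of 20 Paneth cell genes 11 rose, 12 adjusted over the list alone (median 2.74, camera adjusted p = 0.00277, adjusted p = 0.974 with an estimated correlation), among them Defa24 (3.18 ± 0.71). The camera call of this list was also lost with the correction for GC content and length, at a median of 1.35. Of 26 enteroendocrine genes 9 rose, and 10 rose and 1 fell adjusted over the list alone (median 0.86 but -0.13 on log2(TPM + 1), camera adjusted p = 0.00467, adjusted p = 0.974 with an estimated correlation), such as the hormones Sct (2.87 ± 0.56), Ghrl (2.77 ± 0.57) and Sst (2.71 ± 0.44). The goblet cell products Tff3 (2.42) and Spink4 (2.27), the fatty acid carrier Fabp1 (3.32), the Notch effector Hes1 (3.55), and the regulators Cebpb (5.88) and Zfpm1 (4.54) rose too.

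Of 48 genes of G2 and M phase 26 fell, on either count (median -0.93, camera adjusted p = 1.61e-07, adjusted p = 0.974 with an estimated correlation), among them the mitotic kinase Plk1 (-1.51 ± 0.25) and the kinesin Kif20a (-2.60 ± 0.45). Of 47 genes of DNA replication, G1 and S phase 17 fell, 18 adjusted over the list alone (median -0.71, camera adjusted p = 0.00141, adjusted p = 0.974 with an estimated correlation), such as Mcm2 (-1.65). Without AIN 2 this median was -0.52 (camera adjusted p = 0.0545). Of 53 DNA repair genes 1 rose and 20 fell, 24 adjusted over the list alone (camera adjusted p = 0.000298, adjusted p = 0.974 with an estimated correlation), and of 24 TCA cycle genes 13 fell, 14 adjusted over the list alone (camera adjusted p = 0.00021, adjusted p = 0.974 with an estimated correlation). Sdha (-1.46) and Pdha1 (-1.32) were among the latter. The interferon-induced Bst2 (-3.74 ± 0.57), the chaperone Pdia3 (-2.76 ± 0.33), the peptide transporter Tap2 (-2.74), the desaturase Fads2 (-2.03) and the folate carrier Slc19a1 (-1.25) fell. Without AIN 3 or AINlowVitD 3 the numbers called were 3210 and 3326.

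AIN_VdrKO against AIN asks what loss of the vitamin D receptor does on the control diet. Vdr itself read 297, 482 and 247 CPM in the libraries labelled AIN_VdrKO and 338, 373 and 746 in AIN (-0.56 ± 0.37, adjusted p = 0.348). Counts over a whole gene do not show whether a part of it is deleted, so they neither check nor contradict the label. In these libraries the antimicrobial lectins Reg3b (ENSMUSG00000071356.4) and Reg3g and 6 MHC class II genes rose, and 6 of 23 glycolysis genes and 7 of 24 TCA cycle genes fell, list calls that were lost with an estimated correlation (adjusted p = 0.902). In all, 1194 genes rose and 817 fell, and 7 of 77 spike-ins (9.1%) changed. AIN_VdrKO lay between the sets on the first principal component and in mitochondrial ribosomal RNA, and 796 of its rises and 601 of its falls were shared with AINlowVitD against AIN, a comparison across the sets. Genotype and a part of the set difference therefore cannot be told apart here. Without AIN 1 and AIN 2, which stood nearer to AIN_VdrKO on that component, and NWD1 1, 3701 genes were called, with the lone AIN library assumed to vary like the other groups. On log2(TPM + 1), with a median shift of -0.23, 642 were higher and 708 lower.

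Reg3b changed by 4.55 ± 0.96 (adjusted p = 0.00443), with 44300, 34000 and 20400 CPM in AIN_VdrKO against a mean of 1641 in AIN. Reg3g changed by 3.84 ± 0.93 (adjusted p = 0.0110), from a mean of 1206 to 16140 CPM. Of 22 antimicrobial and acute phase genes 6 rose, 7 adjusted over the list alone (median 1.58, camera adjusted p = 0.0113, adjusted p = 0.902 with an estimated correlation), including the siderophore-binding Lcn2 (9.41 ± 1.27, from 0.0429 to 28.8 CPM) and Duoxa2 (3.05 ± 0.80), a partner of the oxidase that makes hydrogen peroxide. The camera call of this list was lost without AIN 2 (median 1.25, adjusted p = 0.105) or AIN_VdrKO 1 (median 1.67, adjusted p = 0.0504). The goblet cell product Retnlb rose by 5.66 ± 0.75 and the acute phase gene Saa1 by 4.78 ± 1.42, the latter call lost with the correction for GC content and length. The MHC class II list held 11 tested identifiers of 10 genes, since Ciita has 2 of them. Of these 6 rose, 7 adjusted over the list alone (median 2.1, camera adjusted p = 0.0110, adjusted p = 0.902 with an estimated correlation). With each gene taken once the counts were the same and the median was 2.41 (camera adjusted p = 0.0113). Cd74, the invariant chain, had 440, 883 and 18 CPM against a mean of 25.1 in AIN (4.39 ± 0.97, adjusted p = 0.00606), so AIN_VdrKO 3 did not share it. H2-Aa (4.79), H2-Eb1 (3.49) and H2-DMb1 (3.25) rose. The camera call of the MHC class II list was lost without AIN 2, AIN 3, AIN_VdrKO 1 or AIN_VdrKO 2, with medians of 2.03, 2.18, 2.63 and 1.26 and 4, 1, 5 and 3 members rising. Markers of immune cells read 1.68 as the median of 13 T and NK cell genes, 0.89 of 8 B and plasma cell genes and 0.53 of 10 myeloid genes, or 0.35, 0.27 and 0.07 on log2(TPM + 1). The median of 6 erythroid cell genes was larger, at 3.13 (1.11 on log2(TPM + 1)), with 0 passing on either count (camera adjusted p = 0.195) and 1.15, 0.23 and -1.51 log2 CPM in the AIN_VdrKO libraries against -1.97, -3.33 and -2.49 in AIN. This median was also above AIN in AINlowVitD (2.76), NWD1Ca (2.38), NWD1 (2.27), NWD1VitD (1.95) and NWD2 (0.37), so its rise was not particular to AIN_VdrKO. Of the immune cell markers, Igkc, an antibody light chain (6.07 ± 1.48, adjusted p = 0.0113), and Cd14, a myeloid receptor (2.15 ± 0.38, adjusted p = 0.00123), rose, while Ptprc, the common leukocyte antigen, chosen after its value was seen, had -0.62 (adjusted p = 0.627). Cd14 had 22.1, 28.9 and 27.7 CPM in the AIN_VdrKO libraries and Igkc 1.17, 20.6 and 0.092. The T and NK cell median was 0.23 and 0.72 log2 CPM in AIN_VdrKO 1 and AIN_VdrKO 2, the libraries with high Cd74, and -2.9 in AIN_VdrKO 3, against -1.18, -2.48 and -2.38 in AIN. Without AIN_VdrKO 3, 7 of 12 MHC class II identifiers and 6 of 23 antimicrobial genes rose.

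**Figure D5:**
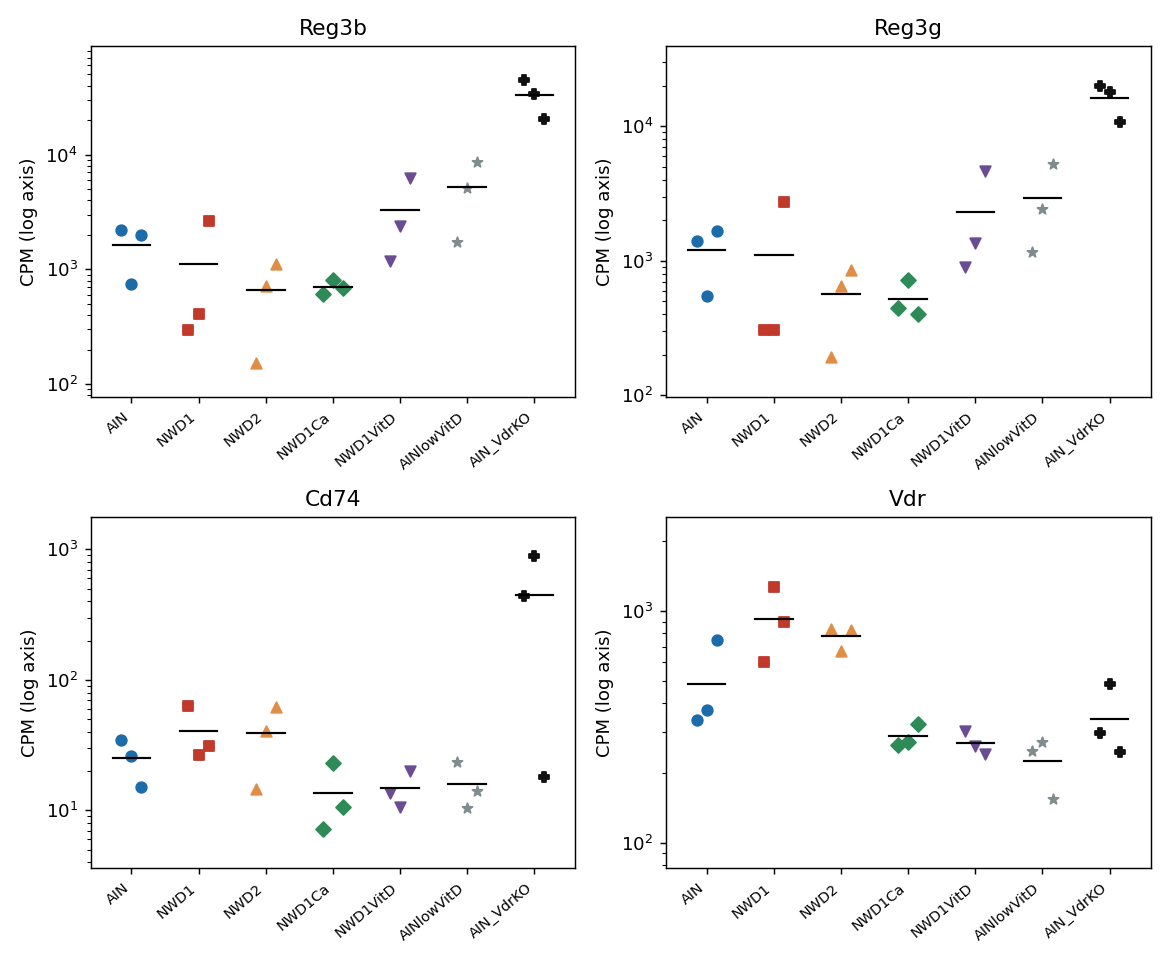
Reg3b, Reg3g, Cd74 and Vdr in CPM per library on log axes, by group, with a line at the group mean. Reg3b is at 20400 CPM or more in each AIN_VdrKO library, Cd74 is high in 2 of the 3, and Vdr in AIN_VdrKO lies in the range of the other groups.

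Of 25 Lgr5 stem cell genes 7 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.92, camera adjusted p = 0.00267, adjusted p = 0.902 with an estimated correlation). The RNA-binding protein Msi1 (2.92 ± 0.51), the receptor regulators Lrig1 (1.62 ± 0.37) and Znrf3 (1.55 ± 0.40, with its call lost after the correction for GC content and length) were among the rises, and Lgr5 had 0.21 (adjusted p = 0.827). Of 25 Wnt targets 5 rose and 1 fell, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.902 with an estimated correlation), such as Sox4 (3.63) and Sp5 (2.36), and without AIN_VdrKO 3 there were 3 rises, 5 adjusted over the list alone. Of 23 glycolysis genes 6 fell, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.000139, adjusted p = 0.902 with an estimated correlation), among them Pkm2 (-1.75), Gpi1 (-1.45) and Eno1 (-1.41). Of 24 TCA cycle genes 7 fell, 14 adjusted over the list alone (camera adjusted p = 1.71e-06, adjusted p = 0.902 with an estimated correlation), such as Pcx (-1.98) and Sdha (-1.29). Of 32 enterocyte genes 3 fell, 1 adjusted over the list alone (median -0.92, camera adjusted p = 0.00229, adjusted p = 0.902 with an estimated correlation), among them Mep1a (-2.08) and Vil1 (-1.45), the latter call lost with the correction for GC content and length, and without AIN_VdrKO 3 there was 1. Of 25 cholesterol synthesis genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.00229, adjusted p = 0.902 with an estimated correlation), such as Acat2 at -1.64. The camera call of the last list was lost without AIN_VdrKO 1, with a median of -0.31 against -0.50 (adjusted p = 0.0513).

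Vitamin D receptor target and calcium transport genes had a median of -0.62 with 1 of 26 rising and 4 falling, 1 and 5 adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.902 with an estimated correlation). The camera call was lost without AIN 3 (median -0.48, adjusted p = 0.198), AIN_VdrKO 1 (median -0.53, adjusted p = 0.0801) or AIN_VdrKO 3 (median -0.94, adjusted p = 0.135). Mt1 rose (2.35 ± 0.51), while the transporters Slc37a2 (-3.69 ± 1.06) and Abcb1a (-1.62 ± 0.51) and the claudin Cldn15 (-1.11 ± 0.33) fell. S100g had -1.75 ± 0.96 (adjusted p = 0.253), and -3.28 ± 1.00 (adjusted p = 0.046) without AIN_VdrKO 1, and Ppargc1a had -0.94 (adjusted p = 0.282). Trpv6 had 0 counts in all 3 AIN_VdrKO libraries and 2, 2 and 0 in AIN, and did not pass (-3.35 ± 2.29, adjusted p = 0.371), so counts this low show no Trpv6 difference between these groups. Against NWD1, which differs from AIN_VdrKO in diet as well, the 0 counts put NWD1 at least 1030-fold higher over a floor of 3 counts for the group. The two-sided 95% counting interval used for the other Trpv6 ratios had a lower end of 836 here. The keratin Krt19 fell by 1.74 and the chaperone Pdia3 by 2.60. The largest falls included Defa21 (-6.07 ± 1.29), the cytochrome Cyp2c55 (-5.65 ± 0.91), the chromatin gene Cbx6 (-5.39 ± 0.41), Serpina1b (-5.01 ± 0.63), Insl6 (-4.86 ± 0.45) and the deiodinase Dio1 (-4.63 ± 0.60). Whether these 6 genes differ with the strain background of the mice or by linkage to the targeted locus was not tested. Without AIN 3 the number of genes called was 992, and it was 383 with only the 2 groups in the fit. AIN_VdrKO held only males and AIN 3 was the only male AIN library. With a sex term, the fit of only the 2 groups therefore compares AIN_VdrKO with AIN 3 alone. Without AIN 3 the AIN libraries were all female, and the sex difference was taken from other groups.

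NWD1Ca against NWD1 asks what added calcium does on the NWD1 diet, across the 2 sets of libraries. Trpv6 fell from 16.8 ± 3.40 CPM (SD, n = 3) to 0.0574 ± 0.0616, with 1, 0 and 4 counts in NWD1Ca. Its log2 fold change was -7.86 ± 1.2 (adjusted p = 0.000321), and the pooled ratio of NWD1 to NWD1Ca was 252 (95% counting interval 108 to 777). Fabp1, Apoc2 and Rbp2 of lipid and retinol handling and the hormones Ghrl, Sst and Gip rose, while 7 of 25 stem cell, 6 of 19 tuft cell and 16 of 47 replication genes fell, and of 41 one-carbon genes 11 fell and 3 rose. These list calls were lost with an estimated correlation (adjusted p = 0.944). In all, 2507 genes rose and 2396 fell, and 54 of 77 spike-ins (70.1%) changed as well. On log2(TPM + 1), with a median shift of -1.15, 827 were higher and 8265 lower.

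Of 26 vitamin D receptor target and calcium transport genes 2 rose and 7 fell, 2 and 9 adjusted over the list alone (median -0.52, camera adjusted p = 0.214). Vdr (-1.62 ± 0.38, adjusted p = 0.00449), Cldn2 (-2.08 ± 0.38) and Ceacam1 (-1.70 ± 0.32) fell with Trpv6, and S100g had 0.45 ± 0.98 (adjusted p = 0.758), which turned to -0.95 on log2(TPM + 1). Ppargc1a had 0.89 (adjusted p = 0.239) and turned to -0.31 on log2(TPM + 1). Of 32 enterocyte genes 10 rose on either count, with a median of 1.26 that turned to -0.12 on log2(TPM + 1) (camera adjusted p = 0.0036, adjusted p = 0.944 with an estimated correlation). Fabp1 rose by 4.95 ± 0.68, from 459.5 to 17840 CPM, and the apolipoprotein Apoc2 (5.42), the retinol carrier Rbp2 (3.15) and Fabp2 (3.08) rose too. Of 26 enteroendocrine genes 11 rose and 1 fell on either count, with a median of 0.90 that turned to -0.18 on log2(TPM + 1) (camera adjusted p = 0.000914, adjusted p = 0.944 with an estimated correlation), such as Ghrl (3.87 ± 0.62), Sst (3.54 ± 0.47) and Gip (3.39 ± 0.59). The antimicrobial genes Leap2 (6.10), Reg1 (3.46) and Reg3a (2.65) rose, as did Il18 (2.55), whose call was lost with the correction for GC content and length. Of 76 oxidative phosphorylation genes 51 rose and 1 fell, 54 and 1 adjusted over the list alone (camera adjusted p = 2.39e-20, adjusted p = 0.944 with an estimated correlation), and of 78 ribosomal protein genes 58 rose, 63 adjusted over the list alone (camera adjusted p = 8.2e-20, adjusted p = 0.944 with an estimated correlation).

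Of 25 Lgr5 stem cell genes 7 fell, 6 adjusted over the list alone (median -0.47, camera adjusted p = 0.0297, adjusted p = 0.944 with an estimated correlation). The camera calls of this list, at a median of -0.42, and of one-carbon metabolism were also lost with the correction for GC content and length. That of the stem cell list was lost without NWD1 1 (median -0.34, adjusted p = 0.0795) or NWD1Ca 1 (median -0.38, adjusted p = 0.0623). Tnfrsf19 (-2.48 ± 0.50), the granule protein Olfm4 (-2.16 ± 0.56), the Wnt feedback ligase Rnf43 (-1.52 ± 0.36) and Slc14a1 (-1.31) were among the falls. Lgr5 had -1.35 ± 0.52 (adjusted p = 0.0546), and -1.55 ± 0.54 (adjusted p = 0.0341) without NWD1 1. The NWD1 1 library had the lowest Lgr5 of its group, at 44.8 CPM against 59.9 in NWD1 2 and 81.7 in NWD1 3, so leaving it out favours a larger fall. Of 19 tuft cell genes 6 fell, 7 adjusted over the list alone (median -1.41, camera adjusted p = 0.00526, adjusted p = 0.944 with an estimated correlation), such as the tuft cell factor Pou2f3 (-1.94) and the taste channel Trpm5 (-2.06). Without NWD1 3 this median was -0.74 (camera adjusted p = 0.0611). Of 47 genes of DNA replication, G1 and S phase 16 fell, and 1 rose and 18 fell adjusted over the list alone (camera adjusted p = 0.00682, adjusted p = 0.944 with an estimated correlation), such as Mcm2 (-1.98). Of 48 genes of G2 and M phase 15 fell, 17 adjusted over the list alone (camera adjusted p = 0.00211, adjusted p = 0.944 with an estimated correlation). Of 41 one-carbon metabolism genes 3 rose and 11 fell, 3 and 13 adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.944 with an estimated correlation). Among the falls were Slc19a1 of folate uptake (-2.20 ± 0.29), Phgdh of serine synthesis (-2.49) and Shmt2 (-1.70). Myc (-2.31) and Fads2 (-2.32) fell. Without NWD1 3 the number of genes called was 2524.

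NWD1VitD against NWD1 asks what added vitamin D does on the NWD1 diet, again across the 2 sets. S100g rose by 3.49 ± 0.91 (adjusted p = 0.00536), from 403.4 to 4563 CPM, and had 2.21 ± 0.86 (adjusted p = 0.0611) without NWD1VitD 3. Trpv6 had 27, 29 and 383 counts, or 1.07, 1.02 and 16.8 CPM, and its difference from NWD1 did not pass (-1.50 ± 0.83, adjusted p = 0.159). The pooled ratio of NWD1 to NWD1VitD was 2.86 (95% counting interval 2.58 to 3.17). Both values rested on NWD1VitD 3. Without it Trpv6 fell by 4.07 ± 0.61 (adjusted p = 0.000387) and the ratio was 15.7 (12.1 to 20.9). With all libraries and no filter on low counts it passed as well. Of the lists, 13 of 20 Paneth cell, 14 of 26 enteroendocrine and 17 of 32 enterocyte genes rose, the last with the fatty acid carriers Fabp1 and Fabp2 among them, while 36 of 48 genes of G2 and M phase fell, and of 25 stem cell genes 11 fell and 1 rose. These list calls were lost with an estimated correlation (adjusted p = 0.854 to 0.960). In all, 3198 genes rose and 3306 fell, and 54 of 77 spike-ins (70.1%) changed as well. On log2(TPM + 1), with a median shift of -1.38, 699 were higher and 9678 lower.

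Of 26 vitamin D receptor target and calcium transport genes 8 rose and 5 fell on either count, with a median of 0.69 that turned to -0.64 on log2(TPM + 1) (camera adjusted p = 0.794). Vdr (-1.78 ± 0.36, adjusted p = 0.000888) and Cldn2 (-2.30 ± 0.35) fell and Mt1 rose (2.16 ± 0.48, adjusted p = 0.00179). Of 20 Paneth cell genes 13 rose on either count (median 3.66, camera adjusted p = 0.000201, adjusted p = 0.916 with an estimated correlation), such as Defa22 (5.85 ± 1.06), Defa20 (5.02 ± 0.97) and Defa5 (4.77 ± 0.93). The median of this list was 7.17, 9.27 and 10.3 log2 CPM in the NWD1VitD libraries and 7.16, 4.92 and 5.49 in NWD1. Of 26 enteroendocrine genes 14 rose and 1 fell, 16 and 1 adjusted over the list alone (median 1.55, camera adjusted p = 1.73e-07, adjusted p = 0.854 with an estimated correlation), among them Ghrl (4.30), Sst (4.22), Gip (3.96) and Sct (3.79). Of 32 enterocyte genes 17 rose, 20 adjusted over the list alone (median 1.82, camera adjusted p = 1.71e-06, adjusted p = 0.916 with an estimated correlation), with Apoc2 at 6.33, Fabp1 at 5.58 ± 0.66 and Fabp2 at 3.71. The Paneth cell, enteroendocrine and enterocyte medians were 1.70, 0.21 and 0.30 on log2(TPM + 1). Leap2 (6.93), Reg1 (3.92), Reg3a (3.84) and Tff3 (3.13) rose too. Of 76 oxidative phosphorylation genes 52 rose and 3 fell, 53 and 4 adjusted over the list alone (camera adjusted p = 3.46e-16, adjusted p = 0.854 with an estimated correlation), and of 78 ribosomal protein genes 57 rose, 61 adjusted over the list alone (camera adjusted p = 8.72e-16, adjusted p = 0.916 with an estimated correlation).

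Of 25 Lgr5 stem cell genes 1 rose and 11 fell on either count (median -0.79, camera adjusted p = 0.00357, adjusted p = 0.960 with an estimated correlation), among them Tnfrsf19 (-2.71), Slc14a1 (-2.16), Aqp4 (-1.93) and Lgr5 itself (-1.71 ± 0.50, adjusted p = 0.0117). The call of Lgr5 was lost without NWD1 3 (-1.23, adjusted p = 0.0801) or NWD1VitD 2 (-1.55, adjusted p = 0.0627). Of 48 genes of G2 and M phase 36 fell, 38 adjusted over the list alone (median -1.23, camera adjusted p = 6.26e-13, adjusted p = 0.854 with an estimated correlation), such as Kif20a (-3.29 ± 0.46), Aurkb (-2.22 ± 0.30) and Plk1 (-2.09 ± 0.25). Of 47 genes of DNA replication, G1 and S phase 31 fell, 32 adjusted over the list alone (camera adjusted p = 1.42e-09, adjusted p = 0.916 with an estimated correlation), and of 53 DNA repair genes 1 rose and 35 fell, 1 and 38 adjusted over the list alone (camera adjusted p = 6.82e-08, adjusted p = 0.854 with an estimated correlation), with Mcm5 at -2.15 and Fancd2 at -2.54. Of 41 one-carbon genes 4 rose and 17 fell, 4 and 19 adjusted over the list alone (camera adjusted p = 0.00716, adjusted p = 0.854 with an estimated correlation), with Phgdh at -2.80 and Slc19a1 at -2.16. Myc fell by 2.90. Ppargc1a had 0.92 (adjusted p = 0.17) and turned to -0.44 on log2(TPM + 1).

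Set beside AIN rather than NWD1, NWD1Ca had 2445 genes higher and 2740 lower (992 and 6060 on log2(TPM + 1)), and NWD1VitD 2493 and 3290 (674 and 7239), with 61% and 59.7% of spike-ins changed. Trpv6 had 1.55 ± 1.58 (adjusted p = 0.48) in NWD1Ca and rose by 7.90 ± 1.25 (adjusted p = 0.000329) in NWD1VitD. Most of the NWD1VitD mean came from NWD1VitD 3, and without it the rise was 5.66 ± 0.70 (adjusted p = 0.000175). Vdr had -0.71 (adjusted p = 0.146) in NWD1Ca and -0.87 (adjusted p = 0.0605) in NWD1VitD, Lgr5 -0.12 (adjusted p = 0.885) and -0.47 (adjusted p = 0.484), and Ppargc1a -0.83 (adjusted p = 0.259) and -0.81 (adjusted p = 0.243). S100g rose in both, by 2.97 ± 0.90 (adjusted p = 0.0173) and 6.01 ± 1.06 (adjusted p = 0.000519), the former at 2.73 ± 1.03 without AIN 3 (adjusted p = 0.0617) and 2.59 ± 0.94 without NWD1Ca 3 (adjusted p = 0.06), where it did not pass. In NWD1VitD it had 1680, 2960 and 9050 CPM, so part of that rise came from NWD1VitD 3. Of 38 interferon response genes 26 fell in NWD1Ca and 20 in NWD1VitD, 28 and 21 adjusted over the list alone. Camera gave adjusted p = 1.16e-08 for NWD1Ca and 1.79e-06 for NWD1VitD, with adjusted p = 0.74 and adjusted p = 0.693 with an estimated correlation. Of 24 TCA cycle genes 17 and 20 fell, 20 in both adjusted over the list alone. Camera gave adjusted p = 4.47e-07 and 4.22e-08, with adjusted p = 0.74 and adjusted p = 0.693 with an estimated correlation. Without NWD1Ca 3 the first comparison called 3295 genes, and the second called 3556 without NWD1VitD 2 and 3851 without AIN 3.

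Relations between comparisons were compared with simulated unchanged groups that share the same control libraries. The log2 fold changes of NWD1Ca and NWD1VitD against NWD1 correlated across genes at 0.90 against 0.42 simulated, with a covariance of 1.91 against 0.17, and 2323 genes rose and 2141 fell in both, where independent lists would share 499.5 and 493.5. NWD1 against AIN and NWD1Ca against NWD1 had -0.49 against -0.52 simulated, with a covariance of -0.63 against -0.20. NWD1 against AIN and NWD1VitD against NWD1 had -0.49 against -0.46, with -0.66 against -0.16. In these 2 pairs the NWD1 libraries enter with opposite sign, so the shared libraries alone give a negative value. AINlowVitD and AIN_VdrKO against AIN correlated at 0.58 against 0.43, with a covariance of 0.81 against 0.16, and shared 796 rises and 601 falls, where independent lists would share 179.7 and 133.1. NWD1 and NWD2 against AIN had 0.41 against 0.53, with a covariance of 0.23 against 0.18, NWD1 and AINlowVitD 0.05 against 0.47 (0.06 against 0.16) and NWD1 and AIN_VdrKO 0.23 against 0.53 (0.23 against 0.20). Genes are not independent replicates, a control group of 3 cannot be split, and part of each excess may come from the shared controls. The simulated groups shared 0 calls on average in every pair. They leave out the effects and independent lists leave out the shared controls, so the excess over either does not show a shared effect. The comparisons AINlowVitD against AIN, NWD1Ca against NWD1 and NWD1VitD against NWD1 all cross the sets, and 1769 genes were higher and 1671 lower in all 3. NWD1Ca and NWD1VitD are also compared with the same NWD1 libraries. How much of this overlap comes from the set difference cannot be told. AIN_VdrKO lay between the sets, so the calls it shared with AINlowVitD cannot be told apart from the set difference either.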

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

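Chosen only after the result was seen were the tests of the diets alone, of low RNA input, of fewer enterocytes, of the set difference for the AIN_VdrKO genes and of immune cells, and the corrections for GC content and length and the spike-in fits were added after the data were seen.

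Spike-in RNAs, which no comparison of genes uses, took a larger share of all counts in 10 libraries than the highest AIN share of 5.18%. The share was 24.7% in NWD1 1, 20.4% in NWD1 2, 5.24% in NWD1 3 and 6.48% in NWD2 2. It was 6.24% in NWD1Ca 2, 5.59% in NWD1Ca 3, 5.31% in NWD1VitD 1, 5.42% in NWD1VitD 2, 5.59% in NWD1VitD 3 and 5.74% in AIN_VdrKO 1.

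The calls of 5030 genes in AINlowVitD against AIN and 4903 in NWD1Ca against NWD1 went with a first principal component that separated AINlowVitD, NWD1Ca and NWD1VitD from AIN, NWD1 and NWD2. Of 77 spike-ins, 81.8% differed in relative abundance between the same sets of libraries, so a difference in library preparation or sequencing is a candidate explanation for a part of these calls. The tables argue against GC content and length as the whole cause, since 78.1% of the genes called in AINlowVitD against AIN were still called in the same direction after that correction. AINlowVitD and NWD1Ca, which differ in base diet, differed in 0 genes by edgeR, with 209 at an unadjusted p under 0.05 and no other tool run. This count decides little about the diets alone. It was chosen after these groups were seen to lie together, and AIN and NWD1, also on different base diets, differed in 123 genes. The spike-ins, which no diet can change, argue against diet as the only difference between the sets. How much of each comparison across the sets comes from the diet stays open, since set and diet cannot be told apart there.

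Enterocyte genes were lower in NWD1 than in AIN, with a median log2 fold change of -2.15. GC content and length as the cause are argued against by a median of -2.02 after the correction. Low RNA input could have lowered them in NWD1 1 and NWD1 2, and NWD1 3, the 1 NWD1 library with under 20% spike-in counts, stood at 7.47 against a lowest AIN value of 8.64 with an SD of 0.20, but NWD2 1, with 0.985% spike-in counts, stood at 6.63, and 1 library decides nothing. Fewer enterocytes among the sorted cells would raise the markers of other cells alike; the medians of the other cell types spanned 1.15, from -0.14 for enteroendocrine to 1.01 for Lgr5 stem cell genes, while the gap between these lists overlapped between AIN (0.08, 1.26 and 0.45) and NWD1 (2.32, 4.03 and 0.16). Fewer enterocytes and lower expression in each cell therefore cannot be told apart, and an effect of the diet stays open as well.

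Reg3b, Reg3g and MHC class II genes were higher in the libraries labelled AIN_VdrKO than in AIN. Against AINlowVitD the MHC class II genes had a median of 2.77 and Reg3b and Reg3g a median of 2.68. The SE was 0.87 for Reg3b and for Reg3g, and neither Reg3b (adjusted p = 0.0805, edgeR) nor Reg3g (adjusted p = 0.118, edgeR) passed there. The medians go against the set difference alone, but the genes were chosen for being high in AIN_VdrKO. Cd74 of AIN_VdrKO 3, at 18 CPM, lay within the AINlowVitD values of 23.3, 10.4 and 14.1. AIN_VdrKO also differed from AIN in 7 and from AINlowVitD in 36 of 77 spike-ins, so a preparation difference of its own is not excluded. Immune cells carried through the sort cannot be told apart from expression by the epithelium, since T and NK cell genes had a median of 1.68 against AIN, and were high in the same AIN_VdrKO 1 and AIN_VdrKO 2 as Cd74, and Igkc (6.07) and Cd14 (2.15) rose, while Ptprc had -0.62 and most of these markers lay near the floor. Erythroid cell genes, which mark blood, had a larger median of 3.13 with 0 of 6 passing, and were higher in AIN_VdrKO 1 and AIN_VdrKO 2 than in AIN_VdrKO 3 as well. Their rise was not particular to AIN_VdrKO. Against AIN the median was also 2.76 in AINlowVitD, 2.38 in NWD1Ca, 2.27 in NWD1 and 1.95 in NWD1VitD, with 0.37 in NWD2. In AIN_VdrKO against AINlowVitD it was 0.90. Loss of the receptor, the genotype on the label, stays among the open explanations and was not tested beyond these comparisons.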

How the results depend on the processing

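The fits with all 9 first-set libraries, without the NWD1 libraries with over 20% spike-ins, without AIN 1, AIN 2 and NWD1 1, and with the correction for GC content and length, and all fits of NWD1VitD against NWD1Ca and of AIN_VdrKO against AINlowVitD, were chosen only after the results were seen. In counts simulated for NWD1 against AIN, edgeR recovered 13 of 100 genes changed 2-fold; the other comparisons were not simulated.

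Genes called in NWD1 against AIN numbered 123, and 969 with no filter, 390 with no sex term, 13 with only the 2 groups, 3 in the first-set fit, 1 without the high spike-in libraries, 802 with DESeq2, 232 on log2(TPM + 1), and 0 to 274 with 1 library left out (0 without AIN 1, 1 without NWD1 2, 18 without NWD1 1, 48 without AIN 3, 274 without NWD1 3). NWD2 against AIN had 0 by edgeR (1099 at an unadjusted p under 0.05), 157 with no filter, 4 with DESeq2, and 0 to 840 with 1 library left out (840 without AIN 3). AINlowVitD against AIN had 5030, 8101 on log2(TPM + 1), 8645 on log2(TPM + 0.1), and 3210 (without AIN 3) to 4945, with 3326 without AINlowVitD 3. AIN_VdrKO against AIN had 2011, 383 with only the 2 groups, 1336 on log2(TPM + 0.1), and 992 (without AIN 3) to 2654. NWD1Ca against NWD1 had 4903, 9092 on log2(TPM + 1), 9111 on log2(TPM + 0.1), and 2524 (without NWD1 3) to 5808. NWD1VitD against NWD1 had 6504, 10377 on log2(TPM + 1), 10504 on log2(TPM + 0.1), and 4864 to 6889. NWD2 against NWD1 had 1, 842 with no filter, 2 with only the 2 groups, 0 without the high spike-in libraries, 344 with DESeq2, 27 on log2(TPM + 1), 28 on log2(TPM + 0.1), and 0 (without NWD2 2 or NWD2 3) to 343 (without NWD2 1), with 337 without NWD1 3. NWD1Ca against AIN had 5185 and 3295 (without NWD1Ca 3) to 4901. NWD1VitD against AIN had 5783 and 3556 (without NWD1VitD 2) to 5700, with 3851 without AIN 3. NWD1VitD against NWD1Ca had 0 by edgeR (372 at an unadjusted p under 0.05), 117 with no filter, 3 with DESeq2, and 0 with any library left out. AIN_VdrKO against AINlowVitD had 492, 1448 with no filter, 1315 with no sex term, 4 with only the 2 groups, 1166 with DESeq2, 5155 on log2(TPM + 1), 6293 on log2(TPM + 0.1), and 130 (without AIN_VdrKO 3) to 1941 (without AIN_VdrKO 1), with 133 without AINlowVitD 3, 140 without AIN_VdrKO 2 and 222 without AINlowVitD 1. Without AIN 1, AIN 2 and NWD1 1, NWD1 against AIN called 0 (2579 at an unadjusted p under 0.05), AIN_VdrKO against AIN 3701 and NWD2 against NWD1 2. In these fits AIN, and without the high spike-in libraries NWD1, holds 1 library, assumed to vary like the other groups. Fits with fewer libraries have less power. AIN_VdrKO held only males, so with the sex term its fits with only the 2 groups compare it with the lone male library of the other group, AIN 3 or AINlowVitD 3. For the other settings the cause was not tested.

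Deviations of same-numbered libraries correlated at -0.19 to 0.41, and in no comparison were all pairs over 0.1. In NWD1 against AIN replicates 1, 2 and 3 had 0.32, 0.01 and 0.41. Replicate numbers thus showed no pairing throughout a comparison, but with 3 libraries per group these values cannot exclude it. With the replicate number as a block, AIN_VdrKO against AINlowVitD called 782 genes, and the other counts stayed within 1.5 times, such as 129 in NWD1 against AIN and 5121 in AINlowVitD against AIN. Of 612 values of named genes the block ended 15 calls and added 1, and of 154 list calls it ended 3.

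With no sex term, camera's direction reversed for 2 lists in NWD1VitD against NWD1Ca, interferon response, whose median went from 0.30 to -0.08, and cytosolic ribosomal protein, whose median went from -0.20 to -0.01, and the cause was not tested. With 1 library left out, 62 of the 154 list calls were lost for at least 1 choice of library, 4 of them with a change of direction. These 4 were tuft cell in NWD2 against AIN (-0.19 without NWD2 2, to 1.45), cytosolic ribosomal protein in AIN_VdrKO against AIN (0.03 without AIN 3, to 1.03), enteroendocrine cell in NWD2 against NWD1 (-0.25 without NWD1 2, to 1.09), and dissociation stress in NWD1VitD against NWD1Ca (-0.58, to 0.11 without NWD1Ca 2). All 154 list calls were lost with an estimated correlation, 25 with the correction for GC content and length, 6 with no sex term and 2 with DESeq2 size factors. Of the named genes, calls were lost for 53 with that correction, 22 with no filter, 10 with no sex term and 4 with DESeq2 size factors.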

Other observations

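Both comparisons described first were chosen only after the data were seen, as was the choice of the genes named in them; the counts over other splits of the libraries were set in advance.

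NWD1VitD and NWD1Ca lie in the same set of libraries, and 0 of 77 spike-ins differed between them. No gene passed by edgeR, with 372 at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma on log2(TPM + 1). Trpv6 had 27, 29 and 383 counts in NWD1VitD and 1, 0 and 4 in NWD1Ca, a pooled ratio of 88.2 (95% counting interval 37.5 to 273) that rests mostly on NWD1VitD 3 and was 16 (6.47 to 51.2) without it, and a log2 fold change of 6.36 ± 1.31 (adjusted p = 1, edgeR). S100g had 3.04 ± 0.99 (adjusted p = 1). It stood at 1680, 2960 and 9050 CPM in NWD1VitD and 773, 292 and 1010 in NWD1Ca, so part of that difference came from NWD1VitD 3 as well. Paneth cell genes had a median of 1.61, with 5 higher adjusted over the list alone (camera adjusted p = 7.16e-23, adjusted p = 0.126 with an estimated correlation). The groups overlapped, at 7.17, 9.27 and 10.3 log2 CPM in NWD1VitD and 6.21, 6.68 and 7.18 in NWD1Ca, so that difference rests on NWD1VitD 2 and NWD1VitD 3. Genes of G2 and M phase had -0.76 (camera adjusted p = 1.35e-34, adjusted p = 0.126 with an estimated correlation). Vitamin D receptor target and calcium transport genes had 0.43, with 1 higher adjusted over the list alone (camera adjusted p = 5.87e-10, adjusted p = 0.125 with an estimated correlation), and overlapped as well, at 5.24, 5.05 and 5.77 against 5.2, 4.22 and 5.02.

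AIN_VdrKO against AINlowVitD had 110 genes higher and 382 lower (4830 and 325 on log2(TPM + 1)), with 46.8% of spike-ins changed and 130 genes called without AIN_VdrKO 3, 133 without AINlowVitD 3, 140 without AIN_VdrKO 2, 222 without AINlowVitD 1 and 1941 without AIN_VdrKO 1. S100g was lower (-5.03 ± 1.04, adjusted p = 0.0128, edgeR), at -4.69 ± 1.19 without AIN_VdrKO 2 (adjusted p = 0.0621) and -4.54 ± 1.11 without AIN_VdrKO 3 (adjusted p = 0.0651), where the fold stayed near that value but did not pass. It was highest in AIN_VdrKO 1, at 46 CPM against 9.48 and 4.44 in the other AIN_VdrKO libraries. Lcn2 (8.91 ± 1.35), Cd74 (5.01 ± 0.98) and Retnlb (3.46 ± 0.71) were higher. Cd74 had 440, 883 and 18 CPM in AIN_VdrKO and 23.3, 10.4 and 14.1 in AINlowVitD, so AIN_VdrKO 3 did not share its rise. Of 11 identifiers of 10 MHC class II genes 6 were higher, and 7 higher and 1 lower adjusted over the list alone (median 2.77, or 3.21 with each gene taken once, camera adjusted p = 0.000402, adjusted p = 0.701 with an estimated correlation). Several genes were lower in AIN_VdrKO than in both reference groups. Insl6 had a mean of 0.969 ± 0.18 CPM (SD, n = 3) against 26.95 in AIN and -6.29 ± 0.46 against AINlowVitD, Cbx6 0.430 against 15.17 and -4.31 ± 0.41, and Dio1 3.27 against 95.33 and -3.90 ± 0.57. Serpina1b had -4.81 ± 0.62, Cyp2c55 -4.23 ± 0.86 and Defa21 -9.49 ± 1.43 against AINlowVitD. Strain background and linkage to the targeted locus were not tested for these 6 genes.

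The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In NWD1 against AIN 2 of the 10 splits called as many genes as the real 123, and the highest other, AIN 1, AIN 2 and NWD1 1 against the rest, called 1659, which points to a structure of the samples other than diet. In NWD2 against NWD1 2 of 10 called as many as the real 1, and the highest other, NWD1 1, NWD1 2 and NWD2 1 against the rest, called 221, which also points to such a structure. In AIN_VdrKO against AIN 1 of 10 reached the real 2011, with a highest other of 619. The real split alone, 1 of 10, reached the count in AINlowVitD against AIN (5030, highest other 0), NWD1Ca against NWD1 (4903, highest other 0), NWD1VitD against NWD1 (6504, highest other 1), NWD1Ca against AIN (5185, highest other 0), NWD1VitD against AIN (5783, highest other 0) and AIN_VdrKO against AINlowVitD (492, highest other 0). In NWD2 against AIN and in NWD1VitD against NWD1Ca all 10 splits called the real 0, with a highest other of 0.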
